A study of Caenorhabditis elegans with 2 samples.

How the data were processed

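The data were peak lists from ChIP-seq of eGFP-tagged CEH-82 in whole L2 larvae of *C. elegans* strain OP212, with 2 biological replicates per the labels. The labels give an extrachromosomal transgene, mixed sex and a fragment size range for the libraries. They name CEH-82 as the antibody target and do not describe the antibody further. Both samples formed 1 group, so no comparison between conditions was made.

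Per the text deposited with the samples, the authors aligned the reads of each replicate, called peaks with background for each replicate and for both together against a control alignment, and kept from the pooled list the regions that passed an irreproducible discovery rate (IDR) threshold. The aligner, the peak caller, the IDR threshold and the treatment of duplicate reads are not given in the sources used here, and the control alignment was not analysed here. The lists were deposited on builds ce11 and ce10. Each row holds an interval, a summit position, a signal value and a significance. The signal value is a score that the authors deposited as their caller gave it, with no stated scale. The significance is, per the deposited format, the −log10 of a q-value, and it was 2.46 to 2.93 in the thresholded ce11 list, that is q from 0.00349 to 0.00117. The column for an unadjusted p-value held only a placeholder in every deposited list. The lists hold no counts of reads, so the depth per sample is unknown, and no interval that needs it is given. The replicate lists have 30000 rows each and so hold background regions by construction.

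The thresholded ce11 list has 537 rows, 526 of them 264 bp wide, and signal values from 21.1 to 211 with a median of 28.2. These rows were the 537 strongest of the 9070 pooled rows (5.92%), so every comparison with the remaining candidates is also one of stronger with weaker regions. The 8 pooled rows that overlap a reproducible peak without being one were left out, which left 8525 candidates. Only the 6 nuclear chromosomes appear in the lists.

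Summits were annotated with Ensembl release 115 genes on WBcel235, the assembly that ce11 names, and the sequence was taken from the same assembly. Coordinates are on ce11 and 1-based. The ce10 lists were used only for counts, replicate agreement and chromosome shares. A summit was in a promoter window when it lay 1000 bp upstream to 200 bp downstream of a gene start, and a gene was bound when a reproducible summit lay in its window. A gene could have several peaks and a peak several genes. Motifs and 6-mers were searched on both strands in 201 bp windows centred on the summit.

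Replicate agreement was the share of the 537 strongest peaks of replicate 1 with a summit within 100 bp of the 537 strongest of replicate 2, against 1000 random draws. Shares were compared between reproducible peaks and remaining candidates by two-sided Fisher's exact tests, with conditional odds ratios and exact 95% limits. Adjustment was by Benjamini-Hochberg over 22 gene lists, 23 motifs, 2080 6-mers, 6 chromosomes or the annotation classes, with a threshold of 0.05. The background for gene lists was the 6257 genes with any pooled summit in the window. These tests treat peaks and genes as units and do not measure the spread between animals or cultures. Equality of 2 odds ratios was tested with Zelen's exact test and the Breslow-Day test. GC content and rank correlation used two-sided permutation tests with 100000 resamples. Candidates of equal GC content were 537 remaining candidates, each the nearest in GC percent to 1 peak and used once (mean 46.7% in both sets). They had a median signal value of 16.9, against 8.85 for all remaining candidates, and being fewer they also give less power.

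The gene lists, motifs, tests and rule for named genes were fixed before the data were examined. The text names the target gene, the 20 strongest reproducible peaks with the genes whose window holds the summit or else the nearest gene start, up to 4 genes with the strongest peak per gene list, the fixed motifs, and the 10 6-mers with the smallest adjusted p. Genes named outside this rule are marked as such. Alternatives tried were other summit distances, promoter windows, sequence windows, builds and backgrounds, the stronger 50% of the peaks or of the candidates, each replicate alone in place of the thresholded list, and candidates of equal GC content. For the last, the motif and 6-mer tests were planned and those of promoters and gene lists were added after the data were seen, as were leaving out X or the peaks at ribosomal protein promoters.

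The gene list test was tested on simulated data: over 20 simulated sets with 3 lists given 10 times the weight, it recovered 60 of 60 changed lists and called 0 others, and it called 1 list when nothing had been changed. With 5 6-mers inserted into 20% of windows, the 6-mer test recovered all 5 and called 46 others, and it called 0 with none inserted. The simulated peaks were drawn at random from the pooled list, apart from the weights. They therefore lack the GC difference of the real peaks and do not measure calls that composition brings. Weights smaller than 10 were not simulated. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and regions were merged with bedtools 2.31.1.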

Results

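Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map where CEH-82 sits on the genome of *Caenorhabditis elegans* larvae at the second stage (L2). CEH-82 is a homeobox protein, a member of a large class of transcription factors that bind DNA through a homeodomain, and here it carried a green fluorescent protein tag (eGFP) expressed from a transgene in strain OP212. Whole animals of mixed sex were used, so a peak can come from any tissue. The series held 1 group with 2 biological replicates, and no other factor, stage or untagged strain was compared. The question was therefore which sites and genes carried peaks, and how they differed from the weaker regions that the peak caller also listed. Per the deposited lists on build ce11, each replicate had 30000 regions, the alignments of both replicates together gave 9070 regions, and 537 of these passed the authors' reproducibility threshold. Those 537 are called reproducible peaks below, and the 8525 pooled regions that did not overlap them are called remaining candidates. The name refers to that threshold only. Within 100 bp, 492 of the 537 had a summit in the replicate 1 list and 531 in that of replicate 2. Only 240 were among the strongest 537 of both lists. The lists give no read counts, so the depth of either library is unknown.

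The strongest sites fell into a group at autosomal promoters and a group on the X chromosome that mostly lay away from promoters. The highest signal value, 211, belonged to a peak at III:10759170-10759324, with its summit at -58 bp from the annotated start of tasp-1, which encodes a threonine aspartase, and at -727 bp from that of K01G5.10 on the other strand. Next among autosomal sites were rpl-3 (169, III:3867508-3867629), cdc-48.1 (153, II:10563521-10563637), whose product is a AAA ATPase that extracts ubiquitinated proteins, and rpl-35 (139, III:7854655-7854734). The others among the strongest 20 were the divergent pairs rpl-15 and K11H12.8, rpl-20 and Y17G9B.5, cap-2 and gmps-1, and rps-12 and ska-3, and the single gene K12H4.5. The rpl and rps genes encode proteins of the large and small ribosomal subunits. All 9 autosomal peaks among the strongest 20 lay in a promoter window, defined as 1000 bp upstream to 200 bp downstream of a gene start. The other 11 were on X, and 8 of these lay outside any promoter window.

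The X sites with the highest signal values were X:14525864-14526017, with 187, and X:6296493-6296611, with 168. The first was at -736 bp from the start of nspc-17. The second lay in an intron, at -3384 bp from the nearest gene start, that of cest-16. Intergenic X sites near F20B6.9 (164), a tRNA gene (160), K02D3.5 (156), gtr-1 (129), F22H10.2 (114), F55G7.5 (94.8) and ZK899.10 (94.3) had their summits between 1372 and 3911 bp from the closest start. The remaining X sites of this group were in the windows of the insulin-like peptide gene ins-39 (117) and the noncoding RNA gene C18A11.13 (113). All 20 peaks were also among the strongest 537 of each replicate taken alone. Signal values are the authors' own per peak and serve only to rank peaks within a list.

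**Figure D1:**
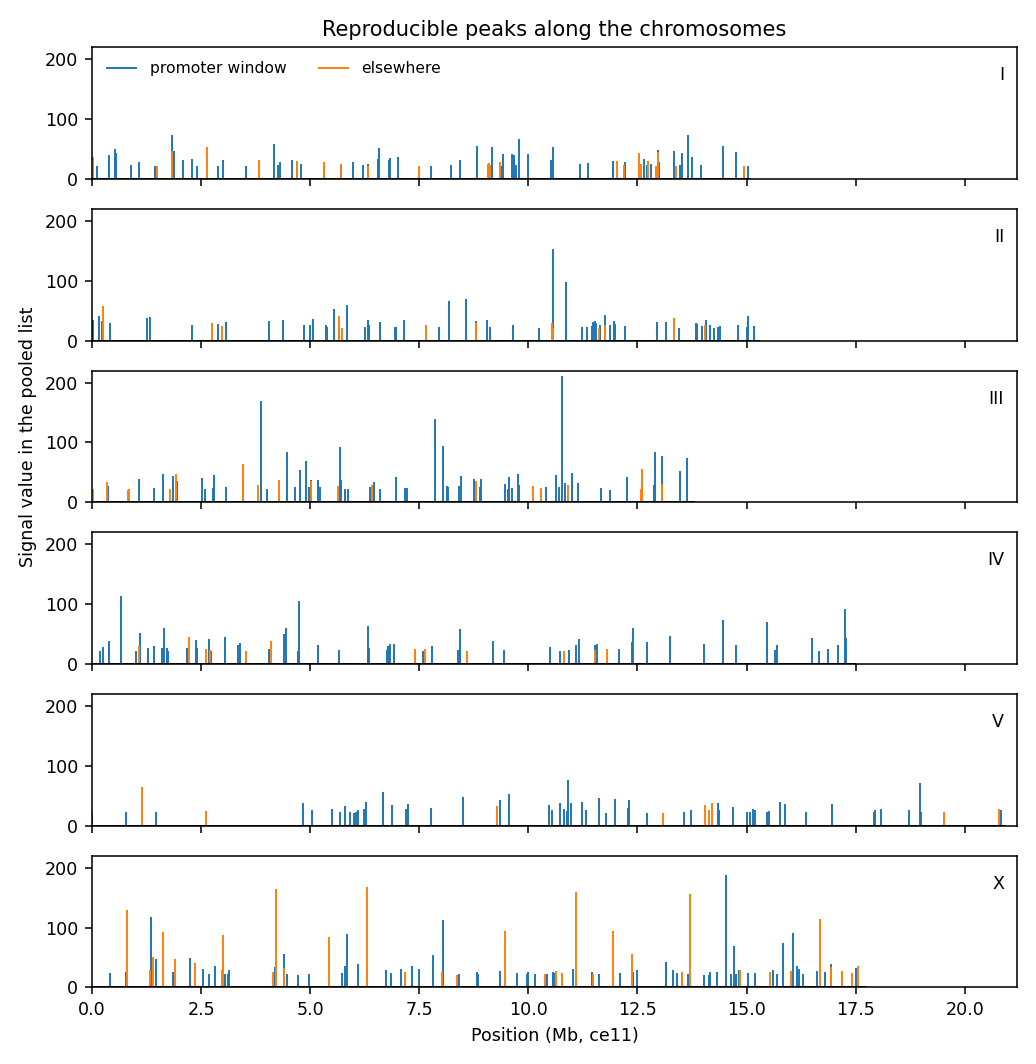
Position of the 537 reproducible peaks along each chromosome (horizontal axis, Mb on ce11) and their signal value in the pooled list (vertical axis). Each line is 1 peak, blue in a promoter window and orange elsewhere. Of the 11 X peaks among the strongest 20 genome-wide, 8 are orange, while all 9 autosomal ones are blue.

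The replicates shared their strongest peaks far more often than random draws did, but their ranks of the reproducible peaks agreed only loosely. Of the 537 strongest peaks of replicate 1, 238 (44.3%) had a summit within 100 bp of one of the 537 strongest of replicate 2. Draws of 537 regions from the full list of replicate 2 shared 1.31% on average and 3.35% at most, giving a one-sided Monte Carlo p of 0.001, the smallest that 1000 draws allow. Signal values in the replicates were compared over the 486 reproducible peaks found in both lists. Spearman's rho across these peaks was 0.30 and Pearson's r was 0.78, with a permutation p of 1e-05 for rho, the smallest that 100000 resamples allow. Peaks are not independent replicates, and they were chosen on the signal of both replicates together, which can itself lower rho, so these coefficients describe the lists only. The pooled ranks followed replicate 2 (rho 0.85) more closely than replicate 1 (rho 0.64), and 441 reproducible peaks were among the strongest 537 of replicate 2 against 301 for replicate 1.

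**Figure D2:**
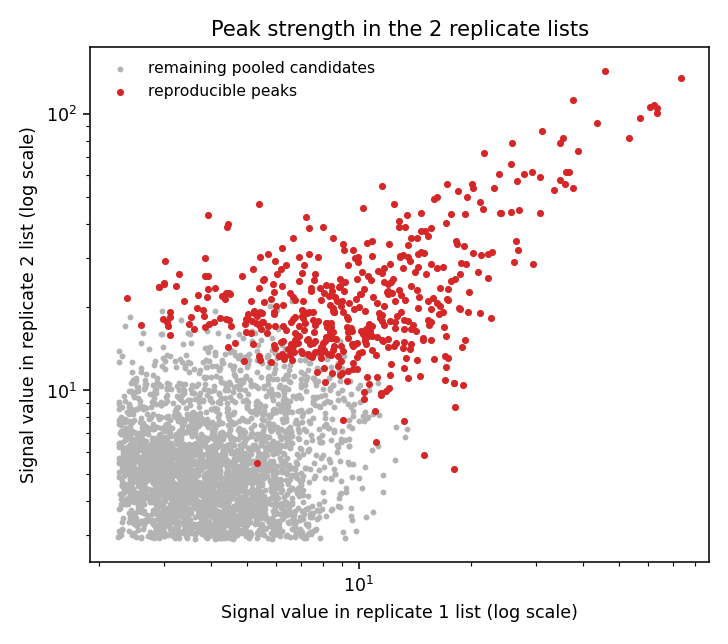
Signal value in the replicate 1 list (horizontal, log scale) against replicate 2 (vertical, log scale) for pooled regions with a summit within 100 bp in both lists. Red points are 486 reproducible peaks and grey points are 3041 remaining candidates. All 20 strongest pooled peaks are among the strongest 537 of both lists, while 441 reproducible peaks are so in replicate 2 and 301 in replicate 1.

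Reproducible peaks mostly sat just upstream of annotated gene starts and were rare in exons away from them. Summits fell in a promoter window for 418 of 537 peaks (77.8%), against 3644 of 8525 remaining candidates (42.7%), an odds ratio of 4.70 with 95% limits of 3.81 and 5.84 (Fisher's exact test, p = 3.47e-58). Outside promoter windows, exons held 2.42% of all peaks against 20.4% of all candidates, introns 8.75% against 22.3%, and intergenic sequence 11% against 14.5%. A higher promoter share lowers the others, so they were also compared among summits outside promoter windows, a test chosen after the data were seen. There exons held a lower share of peaks (10.9% against 35.6%, odds ratio 0.222, limits 0.114 and 0.397, adjusted exact p = 6.31e-09), introns a similar one (39.5% against 39%, 1.02, limits 0.689 and 1.5) and intergenic sequence a higher one (49.6% against 25.4%, 2.89, limits 1.97 and 4.23, adjusted exact p = 4.46e-08). In windows of protein-coding genes the median summit was at -192 bp from the start, and 95.1% of the 347 summits lay upstream. The 2323 candidates in such windows had a median of -247 bp, and 84.9% were upstream. Starts on both strands, as at a divergent gene pair, were present around 142 of the 347 peaks (40.9%) and 356 of the 2323 candidates (15.3%), an odds ratio of 3.82 with limits of 2.98 and 4.91 (Fisher's exact test, p = 1.14e-25). Against candidates of equal GC content, the promoter odds ratio was 1.81 (1.37 to 2.40, Fisher's exact test, p = 1.81e-05) and the divergent one 2.97 (1.98 to 4.49, p = 1.72e-08).

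**Figure D3:**
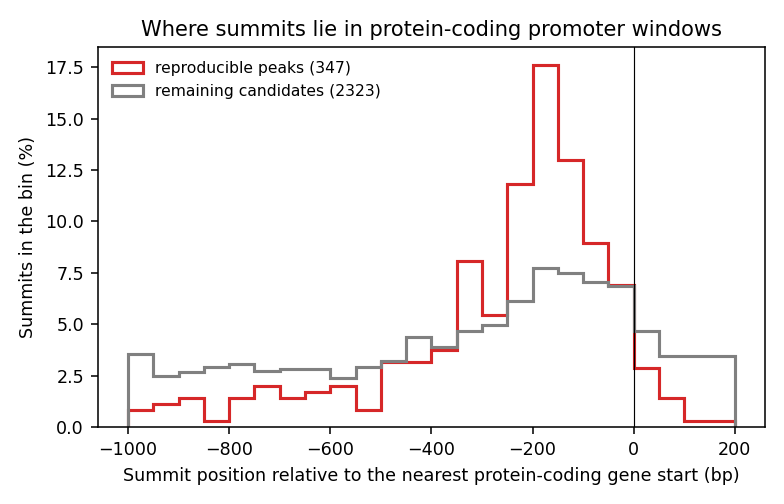
Distance from the nearest protein-coding gene start to the summit (horizontal, bp, negative upstream) and the percent of summits in each bin (vertical). The red line is the 347 reproducible peaks and the grey line the 2323 remaining candidates. The red line is highest near its median of -192 bp.

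Genes of protein synthesis and folding carried reproducible peaks most often. A summit in the promoter window was found for 781 genes, out of 6257 with any pooled region there, and 507 of the 781 were protein-coding. By Fisher's exact test, adjusted over the 22 lists, ribosomal protein genes stood highest, with 40 of 62 bound (64.5%, against 12% of other genes, odds ratio 13.4, limits 7.71 and 23.8, adjusted exact p = 1.45e-20). The highest signal values in this list were at rpl-3, rpl-35, rpl-15 (114) and rpl-20 (106). These 40 genes lay at 37 peaks, since some share 1, and in each pair of gene and peak the summit was upstream of the start, at a median of -292 bp. Of 16 genes for translation factors, 8 were bound (odds ratio 7.07, limits 2.31 and 21.7, adjusted exact p = 0.00144). They included iff-2 (69.2), a form of initiation factor eIF5A, and the elongation factor genes eef-1A.2 (54.1), eef-2 (53.3) and eef-1A.1 (42.3). Of 26 genes listed as chaperones and stress genes, 15 were bound (odds ratio 9.72, limits 4.16 and 23.5, adjusted exact p = 3.66e-07). The leading members were cct-1 (66.3) and cct-8 (51.6), subunits of the cytosolic chaperonin, the mitochondrial chaperonin gene hsp-60 (46.8) and hsp-110 (43.6). The bound members of this list that are not chaperones were gst-27, a glutathione transferase, and tbb-2, a beta tubulin, both named after their values were seen. With genes taken as the nearest start within 5 kb of a summit, this list no longer passed (odds ratio 1.5).

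Further lists with more bound genes than the rest covered RNA processing and the cell cycle. Of 159 genes annotated as snRNA or snoRNA, classes that act mainly in splicing and in rRNA modification, 51 were bound (odds ratio 3.47, limits 2.42 and 4.93, adjusted exact p = 4.9e-10). The bound genes include mir-1831, sup-6 and sup-39, singled out after their values were seen, which carry names of other kinds of gene. Many share a peak with a coding gene, as C06A1.9 does with cdc-48.1, K11H12.13 and K11H12.12 with rpl-15, and F54E7.10 and F54E7.11 with rps-12. With every peak at a ribosomal protein promoter left out, 36 of 140 were bound (odds ratio 2.85, limits 1.88 and 4.24, adjusted exact p = 1.02e-05). Of 25 splicing and RNA binding genes, 9 were bound (odds ratio 3.98, limits 1.54 and 9.60, adjusted exact p = 0.00701), led by snr-4 (45), prp-19 (37.7), snr-1 (31.9) and hrpa-1 (31.6). Of 20 cell cycle genes, 9 were bound (odds ratio 5.79, limits 2.11 and 15.4, adjusted exact p = 0.00144), led by cdc-48.1, the E2F gene efl-1 (36.3), cdk-7 (33.8) and cdk-5 (26.4). In this list cdc-48.1 acts in protein extraction and cdk-5 mainly in neurons. Chemoreceptor genes, which act in sensory neurons, were bound less often than the rest. They had 2 bound of 93, srh-16 (28.8) and sri-5 (25.7), with an odds ratio of 0.152 (limits 0.0181 and 0.567, adjusted exact p = 0.00262). In the stronger 50% of peaks, which are fewer, the splicing (3.89) and cell cycle lists (3.6) no longer passed, nor did the chemoreceptors (0.142).

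The other 15 lists did not pass the test. Homeobox genes had 2 bound of 10, ceh-39 (24.8) and ceh-38 (22.9), and nuclear hormone receptors 4 of 45, with the highest value at nhr-1 (33). The list of bHLH, bZIP and further transcription factor families had 3 of 14, mdl-1 (28.7), atf-6 (28.4) and crh-1 (23.5). The mdl-1 peak had no summit within 100 bp in the replicate 2 list. In the replicate 1 list the crh-1 peak ranked 4511 and the ceh-38 peak 6873. Histones had 4 of 12, with htz-1, which encodes H2A.Z, highest (60.6), and the vacuolar ATPase also 4 of 12, with vha-12 highest (34.3). The odds ratio of both was 3.52, with adjusted p of 0.128. Histones passed with either replicate alone (odds ratio 7.69 to 8.80), and the vacuolar ATPase with replicate 2 alone (10.6) and against all protein-coding genes (4 of 21, odds ratio 9.09, adjusted exact p = 0.00414). With 1 replicate alone the background is the rest of its own list, so these odds ratios can differ for that reason too. For histones, replicate 1 alone gave 4 of 17 against 3.85% of other genes, and the main test 4 of 12 against 12.4%. The proteasome and ubiquitin list had 4 of 24, with rpn-3 highest (43.6), and passed with replicate 1 alone (odds ratio 4.81). Neuronal and synaptic genes had 3 of 19, with snb-1 highest (52.8), muscle genes 2 of 11 (unc-60 and act-4), and germline genes 2 of 14, with puf-9 highest (89.6). The snb-1 peak ranked 6797 in the replicate 1 list and 56 in that of replicate 2, and the act-4 peak 6271 and 380. The vha-12 peak ranked 18518 and 110 in these lists. Collagens and cuticle genes had 1 of 29, which was dpy-23, a clathrin adaptor subunit and not a collagen, and neuropeptides 1 of 10, ins-39. No gene was bound of 19 intestinal, 4 signalling pathway and 1 microRNA genes. The microRNA list matched only 7 genes of the whole annotation, so it says little about that class. Against all protein-coding genes the intestinal list passed as less often bound (0 of 331, adjusted exact p = 0.000838). Transfer RNA genes had 23 of 182, an odds ratio of 1.01 (limits 0.621 and 1.59). They passed as more often bound with replicate 1 alone (1.89), and as less often bound without X (0.323, adjusted exact p = 0.042) and at equal GC content.

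The lists were also compared at equal GC content. Against genes at candidates of equal GC content, ribosomal proteins (40 of 49, odds ratio 3.22, limits 1.52 and 7.62, adjusted exact p = 0.0188) and chaperones and stress genes (15 of 16, odds ratio 10.7, adjusted exact p = 0.0361) still passed the test. The other 4 lists with more bound genes and the chemoreceptors did not. Splicing (6.36), cell cycle (3.17) and translation factor genes (2.82) had only 10 or 11 genes left there, while snRNA and snoRNA genes fell to 1.12. Transfer RNA genes passed there as less often bound (23 of 57, odds ratio 0.458, limits 0.254 and 0.811, adjusted exact p = 0.0367). Genes that share a peak are counted separately, and 237 of the 418 promoter peaks had more than 1 gene in the window, so the p-values of the lists are too small by an unknown amount.

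**Figure D4:**
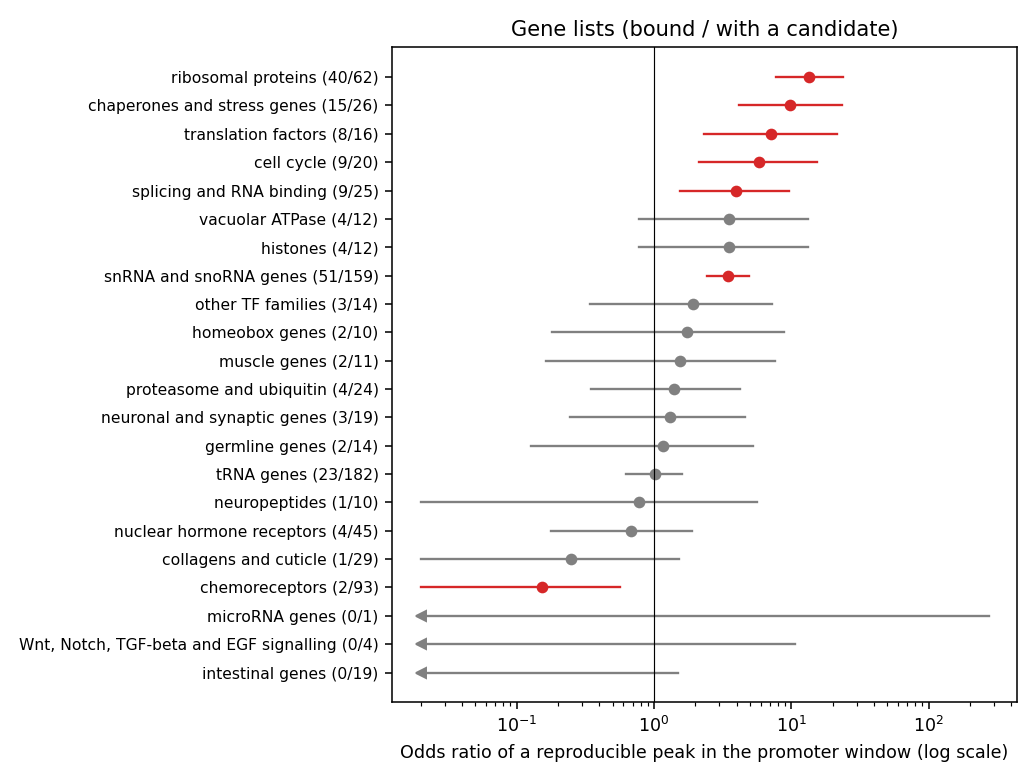
Odds ratio of a reproducible peak in the promoter window for the 22 gene lists (horizontal, log scale), with 95% limits as bars. Numbers beside each list are bound genes and genes with any pooled region, red marks adjusted p under 0.05, and an arrow marks an odds ratio of 0. The highest is ribosomal proteins at 13.4, and the only red list under 1 is chemoreceptors.

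Peaks were spread over all 6 nuclear chromosomes, with fewer on V. Chromosome V held 71 of 537 peaks (13.2%) and 18.6% of candidates, an odds ratio of 0.668 (limits 0.510 and 0.864, adjusted exact p = 0.00905 over 6 chromosomes by Fisher's exact test). The X chromosome held 21.6% of peaks against 19.7% of candidates, an odds ratio of 1.12 (limits 0.899 and 1.39, adjusted exact p = 0.434). With replicate 1 alone the X share passed the test (odds ratio 1.43, adjusted exact p = 0.00165). Peaks on X were in the window of a protein-coding gene less often than autosomal peaks, 56 (48.3%) against 291 of 421 (69.1%), with an odds ratio of 0.418 (limits 0.268 and 0.648, Fisher's exact test, p = 4.63e-05). Candidates showed the same direction, at 20.8% on X and 28.8% on autosomes, and the odds ratio of peaks over candidates was 3.55 on X and 5.52 on autosomes (p for a difference between these odds ratios, 0.0569 by Zelen's exact test and 0.0465 by the Breslow-Day approximation). The comparison of X with autosomes was chosen after the strongest peaks were seen.

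Sequence around the summits was GC-rich, and homeodomain core sites were not more frequent there. The sequence windows of peaks had 46.7% ± 6.93 GC (SD over 537 peaks), against 38.3% ± 7.32 for the 8525 candidates, a difference of 8.38 percentage points (permutation p = 1e-05, the smallest possible). Of 23 fixed motifs, 5 were more frequent in peaks. These were the GAGA repeat GAGAGAGA (14.2% against 3.96%, odds ratio 3.99), the E2F site (18.2% against 8.61%, 2.37), the SP/KLF site (11% against 5.68%, 2.05), the E-box CAGCTG (7.82% against 4.28%, 1.90) and the cut-like site ATCGAT (11.2% against 7.75%, 1.5). There were 8 less frequent motifs, among them GATA (11.5% against 24.5%, 0.402), PBX/HOX (5.77% against 14%, 0.376), TATAAA (9.12% against 18.3%, 0.447) and the homeodomain cores TAATTG or CAATTA (6.33% against 13.7%, 0.427) and TAATCC (1.86% against 6.57%, 0.270). The E-box CAGCTG did not pass with either replicate alone (1.45 to 1.51), in the stronger 50% of peaks (1.71) or in wider windows (1.25), nor the cut-like site in narrower windows (1.21) or the stronger 50% of peaks (1.39). In wider windows TATAAA (0.902), the T-block (0.898) and the SL1-like site (0.895) were no longer less frequent by the test. The core TAATTA was in 5.77% of peaks and 7.88% of candidates (0.716, limits 0.477 and 1.04, adjusted exact p = 0.123), and passed as less frequent with either replicate alone (0.558 to 0.616) and in narrower windows (0.388). The forkhead motif passed as less frequent in the stronger 50% of peaks (0.145) and in narrower (0.147) and wider windows (0.547), and MEIS (0.668) and the nuclear receptor site (0.618) in wider ones. Against candidates of equal GC content, Fisher's exact test called 0 of the 23 motifs in either direction, and 0 had an unadjusted p under 0.05.

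**Figure D5:**
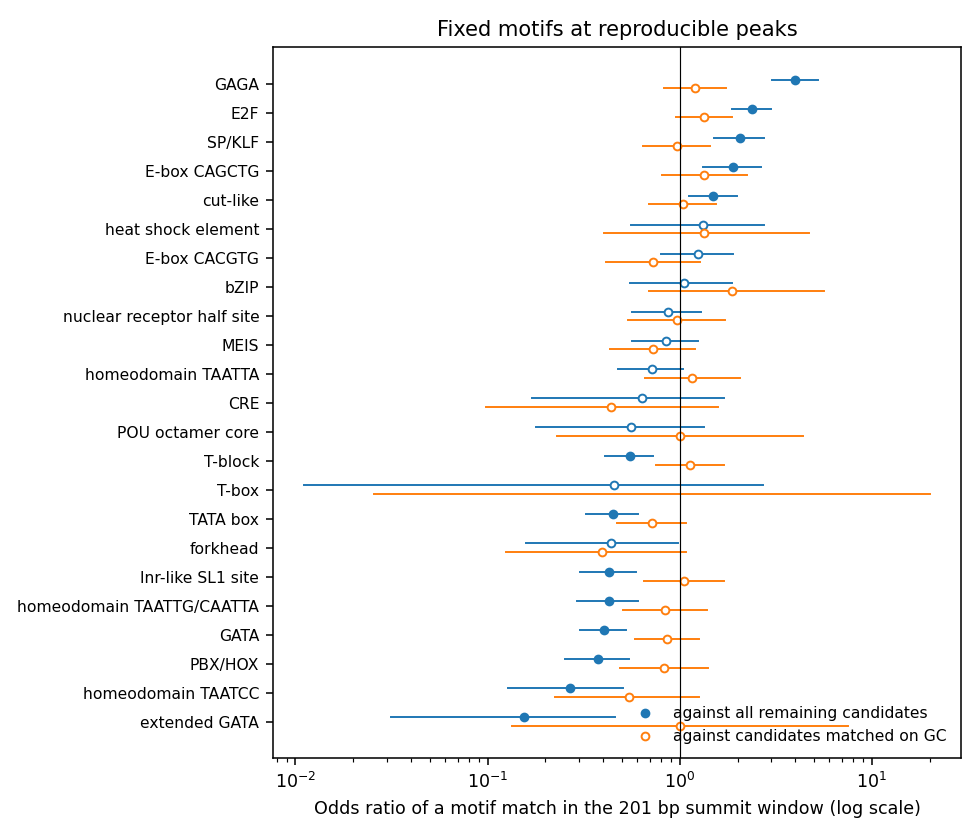
Odds ratio of a motif match in the summit window (horizontal, log scale) with 95% limits for the 23 fixed motifs. Blue is against all remaining candidates and orange against candidates of equal GC content, and filled points have adjusted p under 0.05. GAGA is highest in blue at 3.99, and no orange point is filled.

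An open search over all 6-mers found 523 more frequent in peaks, 318 of them with a CG, and 485 less frequent. Of the 10 with the smallest adjusted p, 8 had a CG and the other two were GAGA repeats. ACGCAG was in 180 peak windows (33.5%) and 8.34% of candidate windows (odds ratio 5.54, limits 4.53 and 6.76, adjusted exact p = 3.24e-52), GACGCA in 33.3% against 8.88% (5.13), and GCGCAC in 24.2% against 4.83% (6.29). CGTCTC, AGACGC, GAGAGA, GAGCGC, ACGCGC, AGAGAG and AGCGCG had odds ratios between 3.57 and 5.51. Several of the 10 overlap and are not independent. GAGACG (the other strand of CGTCTC), AGACGC, GACGCA and ACGCAG each share all but an end base with the next. They were in 190, 161, 179 and 180 peak windows. GAGCGC and AGCGCG overlap in the same way. Whether a longer shared sequence underlies these 6-mers was not tested. Against candidates of equal GC content 12 6-mers were more frequent and 2 less frequent. Of the 10, GACGCA (33.3% against 21.6%, odds ratio 1.81, limits 1.37 and 2.41, adjusted exact p = 0.00635) and GCGCAC (24.2% against 13.4%, 2.06, limits 1.49 and 2.88, adjusted exact p = 0.00503) passed in that test, while ACGCAG had 1.55 (limits 1.18 and 2.04, adjusted exact p = 0.13).

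The gene of the tagged factor, ceh-82 (WBGene00018433, II:1732232-1733291, plus strand), had no reproducible peak within 25 kb. The nearest was 412 kb away. The pooled list had 1 candidate within 25 kb, 14.1 kb from the gene with a signal value of 11.1, where the median 50 kb window of the genome had 4 candidates and 0 reproducible peaks.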

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

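The alternatives that left out the X chromosome or peaks at ribosomal protein promoters, and those that matched GC for promoters and gene lists, were chosen after the data were seen. The count of reproducible peaks (529 to 537), replicate agreement (35.9% to 50.4%), rank correlation (0.28 to 0.36), the promoter odds ratio (1.81 to 5.82), the divergent promoter odds ratio (2.97 to 5.05), the GC difference (4.29 to 12 percentage points) and the absence of peaks at ceh-82 kept their direction and their side of the threshold, where one applies, under each alternative run. The odds ratio of the X share was 1.09 to 1.43 with 1 replicate alone and fell to 0.934 in the upper 50% of peaks. More bound genes were found in 6 lists, against 9 with replicate 1 alone, 8 with replicate 2 alone, 5 against the stronger 50% of candidates, 5 without the peaks at ribosomal protein promoters, 4 in the upper 50% of peaks, 4 with the nearest start and 2 against GC-matched candidates. Fewer were found in 1 list, against 0 in the upper 50% of peaks, 2 against all protein-coding genes, where intestinal genes (0 of 331) joined, and 2 without X, where tRNA genes joined. Motifs more frequent in peaks numbered 5, against 3 in the upper 50% and 0 with GC matching, which also left 0 of the 8 less frequent ones. The 485 less frequent 6-mers became 294 in the upper 50%, and with GC matching 12 6-mers were more frequent and 2 less. The upper 50% holds fewer peaks and GC matching fewer candidates, which lowers the number of calls by construction. A replicate alone also brings the larger background of its own list, so its counts and odds ratios do not show the effect of the replicate by itself. For the other changes the cause was not tested. Of the lists and motifs that passed, 4 reversed with GC matching: chemoreceptors to 1.40, on 3 genes, the SP/KLF motif to 0.963, the T-block to 1.12 and the SL1-like site to 1.05. The chaperone list fell to 1.5 (adjusted exact p = 0.633) when genes were taken as the nearest start within 5 kb. The E-box CAGCTG missed the threshold with either replicate alone (1.45 to 1.51), and splicing genes missed it in the upper 50% (3.89), against the stronger 50% of candidates (2.83) and with the nearest start (3.63). The cut-like motif missed it in the upper 50% (1.39) and in the narrower sequence windows (1.21), and the TATA box (0.902), T-block (0.898) and SL1-like site (0.895) in the wider ones. Other reversals were in lists and motifs that had not passed. With 1 replicate alone, odds ratios were 0 to 0.672 for homeobox genes, 0.724 to 0.888 for muscle, 0.857 to 1.80 for germline, 0.794 to 1.89 for tRNA genes, 0.806 to 1.28 for the T-box motif and 0.853 to 0.961 for the heat shock element. In the upper 50% of peaks they were 0 for homeobox and muscle genes, 1.46 for neuropeptides, 0.820 for neuronal genes and 0.654 for tRNA genes. Against the stronger 50% of candidates they were 1.36 for neuropeptides, 0.956 for the proteasome list, 0.766 for tRNA genes and 0.911 for the bZIP motif. In the narrower promoter window they were 0.719 for germline and 0.778 for tRNA genes, and with the nearest start 0.540 for homeobox and 0 for germline genes. Against all protein-coding genes they were 0.775 for homeobox genes, 0.984 for the bHLH and related families and 0.638 for germline genes. Without X they were 0.879 for homeobox and for muscle genes, 0.781 for the bHLH and related families, 0.540 for neuronal, 0.585 for germline and 0.323 for tRNA genes. With GC matching they were 0.70 for germline genes, 0.934 for the vacuolar ATPase, 0.458 for tRNA genes, 1.16 for TAATTA and 0.730 for CACGTG. The tRNA genes passed in opposite directions, as more often bound with replicate 1 alone and as less often bound without X and with GC matching. The bZIP motif was at 0.614 in the narrower and 0.983 in the wider sequence windows, and the nuclear receptor site at 1.01 in the narrower ones, though it passed as less frequent in the wider ones (0.618), as did MEIS (0.668) and forkhead (0.547). No finite value could be had with GC matching for neuropeptides and the T-box motif, where a cell of the comparison was 0, nor any value for the microRNA and signalling lists, which had no gene left. No paired analysis was possible because the series has 1 group. The depth of the libraries is unknown, so which of these limits come from depth cannot be said.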

Other observations

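The tests of the dosage compensation core, of homeodomain sites and of base composition for the gene lists were chosen after the peaks were seen, as were the comparisons of tRNA genes by chromosome, of the spliced leader genes and of gene name prefixes, and the count of candidates on X. The tests of transgene copies, ribosomal protein genes, base composition for motifs and the leading 6-mer, and the median signal on X were set before their results were seen, though the leading 6-mer and the X pattern were themselves found in the data.

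Transfer RNA genes with a reproducible peak were mostly on X. Of the tRNA genes with any pooled region in the window, 19 of 92 were bound on X (20.7%) and 4 of 90 on autosomes (4.44%), an odds ratio of 5.55 (limits 1.74 and 23.4, Fisher's exact test, p = 0.00134). The 19 genes lay at 13 peaks and the 4 at 3 peaks, so they are not independent. Several of the X peaks, with signal values between 21.9 and 24.0, had no summit within 100 bp in the replicate 1 list. An autosomal one (21.8) also had none there, so some bound genes on both sides rest on replicate 2. Some other X peaks ranked higher in replicate 1 than in replicate 2. Which replicate the contrast leans on was not tested. Of all other genes, 110 of 929 were bound on X (11.8%) and 648 of 5146 on autosomes (12.6%), an odds ratio of 0.932 (limits 0.745 and 1.16). The strongest X peak with a tRNA gene in its window, X:5801169-5801432, had a signal value of 36.4. Among genes for the spliced leader SL2, the short RNA joined to downstream messages of operons, 4 of 8 were bound (odds ratio 7.04, limits 1.31 and 37.9, Fisher's exact test, p = 0.0111): sls-2.1 (59.3), sls-2.4 (58.1), sls-2.2 (53.0) and sls-2.8 (42.5), with summits at -46 to -19 bp from their starts. As the SL2 group was chosen after the peaks were seen, its unadjusted p-value is a description only.

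An unplanned scan of the 64 gene name prefixes with at least 5 protein-coding genes that had a pooled region in the window found 6 past an adjusted p of 0.05. They were rpl (23 of 36) and rps (16 of 25), the heat shock prefix hsp (5 of 5), the elongation factor prefix eef (4 of 5), dnj (5 of 8), which marks DnaJ co-chaperones, and set (4 of 5), which marks SET-domain proteins. The last is in none of the gene lists that passed.

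Many of the strongest X sites, in promoter windows and outside them, carried a sequence known from another setting. GCGCAGGG, the core of the motif at X sites that recruit the dosage compensation complex, was in 15 X peaks (12.9%) and 6 of 1681 remaining X candidates (odds ratio 41.2, limits 14.7 and 132), and in 1 of 421 autosomal peaks. It was in 8 of the 10 strongest X peaks and 7 of the other 106, at a median of 18.5 bp from the summit. Over all X peaks it was in 11 of the 35 outside any promoter window and 4 of the 81 inside one (odds ratio 8.62, limits 2.29 and 40.6, Fisher's exact test, p = 0.00028). Among the 10 strongest it was in 5 of 7 outside and in 3 of 3 inside (odds ratio 0, limits 0 and 13.4). These are too few to tell whether it marks the sites away from promoters there. Among the other X peaks it was in 6 of 28 outside and 1 of 78 inside (odds ratio 20.3, limits 2.28 and 978, Fisher's exact test, p = 0.00125).

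For these X sites, higher coverage of the whole X as their only source was examined through the number of remaining candidates per length. On X this number was 1.14 times that of autosomes (exact limits 1.08 and 1.21). X signals had to be divided by 2.12 to bring X from 11 to 4 of the strongest 20 peaks, and on autosomes a fold of 2.12 changed the number of candidates above the minimum signal 22.1 times, and one of 1.2 did so 2.03 times. If signal values rise in proportion to coverage, higher coverage would thus have given far more X candidates than were listed. The signal value has no stated scale and peaks were called against a control, so that proportion is not known. Coverage as the only source is argued against under that assumption alone. The median signal of X candidates, 0.998 times that of autosomes, decides nothing, since with the minimum signal of the list a fold of 1.5 moved the autosomal median by a ratio of only 1.01. GC content alone is argued against by X candidates of equal GC, of which 1 had the core in a set as large as the X peaks (odds ratio 16.9, limits 2.52 and 725). A hypothesis is that some strong X peaks lie at dosage compensation sites. Whether CEH-82 binds there or such sites yield signal with any antibody cannot be answered with 1 factor and no untagged strain.

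The gene lists may reflect reads drawn to highly transcribed genes whatever the factor, and the ribosomal protein odds ratio of 13.4 is what that explanation needs. Binding of CEH-82 at those promoters would give the same value, so it does not separate them. Against genes at GC-matched candidates, ribosomal proteins fell from 13.4 to 3.22, with limits (1.52 and 7.62) still above 1. GC percent of the summit windows as the whole source is thus argued against for ribosomal proteins. Chaperones and stress genes kept 10.7, but with few genes and very wide limits (1.63 and 451), which argues against it only weakly. Genes that share a peak are counted separately, so these limits are too narrow. Only GC percent was matched, so other features of composition remain open. Of the 12 6-mers still more frequent in peaks after matching, 10 held a CG. GC percent as the source remains open for snRNA and snoRNA genes, which fell from 3.47 to 1.12 (limits 0.698 and 1.84). It is undecided for translation factors (2.82), splicing (6.36) and cell cycle genes (3.17), whose limits span 1 with 10 or 11 genes each. Binding through homeodomain cores was not seen: TAATTA, TAATTG or CAATTA sites were in 11.5% of peaks and 12.3% of GC-matched candidates (odds ratio 0.932, limits 0.632 and 1.37), which leaves a moderate difference either way open.

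Base composition is a candidate source of the motif differences. With GC matching the odds ratio of GAGA fell from 3.99 to 1.2, E2F from 2.37 to 1.33 (limits 0.951 and 1.87), SP/KLF from 2.05 to 0.963 and cut-like from 1.5 to 1.04. CAGCTG, at 1.34 from 1.90, stayed within the limits of its unmatched value and is undecided. The leading 6-mer ACGCAG fell from 5.54 to 1.55 and lost its adjusted p while its limits (1.18 to 2.04) stayed above 1. GACGCA and GCGCAC still passed, so GC percent may not be the whole source for these 6-mers. ACGCAG and GACGCA share all but an end base, so their results are not independent. Matching also takes fewer and stronger candidates as the background, so calls can end for that reason too, and no biological explanation was tested for the motifs.

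Extra copies of the ceh-82 locus on the transgene array were not seen as peaks, with 0 reproducible peaks within 25 kb of the gene. Of the 50 kb windows of the genome, 77.9% held 0 as well, so this absence cannot decide whether such copies added signal.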
